A study of Mus musculus with 8 samples.

How the data were processed

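The data were gene-level values of 8 mouse exon arrays of the tibialis anterior, 4 of fed and 4 of 24 h fasted males aged 8 weeks, each array holding pooled RNA of 3 mice. Per the labels' protocols, total RNA was amplified to cDNA with the SPIA chemistry of NuGEN and labelled with biotin. The authors deposited values on a log scale made with RMA, which corrects the background, normalises between arrays and summarises probes, per the submitters' processing notes; the RMA version and the class of probes used are not given in the sources used here. The log base was read from the values: the deposited values ran from 1.08 to 13.3, which fits log2 of a scanner's range and exceeds what log10 or the natural log of it can reach. The notes also name the human build hg18, with no stated role, so no genome coordinates are printed. Scanner files and detection calls were not used here, so no level is called present or absent, and a low level may be background. RMA compresses differences at low signal, and SPIA amplification can distort the proportions of transcripts, so folds are those of the deposited values.

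The table held 16755 transcript clusters with 0 missing values and 0 unused columns. Gene symbols came from the platform annotation, which can be old: 14996 clusters had 1 symbol, 1019 several and 740 none. Of those with 1 symbol, 14941 matched a mouse RefSeq gene of GRCm38.p6 by Entrez number, and all 14941 had the same symbol there. This compares names only and does not check which gene the probes measure. Clusters with several symbols or none were tested and counted but not named. Clusters of 1 symbol stood for 14860 genes, and a gene with several clusters was represented by the one with the highest mean. Close paralogs, such as metallothioneins, acyl-CoA thioesterases and olfactory receptors, can share probe signal and are uncertain.

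Groups came from the sample titles. Each experiment number pairs a fed with a fasted pool, because the series description has each experiment hold both and sets the fasted level relative to the fed one. In the values the pairing was weak: correlations of paired arrays' deviations from their group means were -0.18, 0.05, -0.14 and 0.44 in experiments 1 to 4, and the consensus correlation within experiments was 0.061. The arrays are separate pools of separate experiments. With experiment as a block, p-values rest on how the difference between fasted and fed pools varied over the 4 experiments. They do not describe the spread between single mice.

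Differences, fasted minus fed, were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on the log2 values with experiment as a block, and p was adjusted by Benjamini-Hochberg over all 16755 clusters, with a threshold of 0.05 and no fold threshold. Standard errors are moderated, with 3 residual and 4.84 prior degrees of freedom. The test, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where stated. Gene lists, 36 in number with 546 different measured genes among them, were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists). They were also tested with camera at an estimated correlation and with fry. The fry test asks whether a list's genes move one way on balance without comparing them with other genes. By fry, 4 lists passed: glucocorticoid response, fatty acid oxidation and ribosome biogenesis higher, and mitochondrial biogenesis lower. The direction given by camera and by fry differed for the erythroid and satellite cell markers, neither of which passed. The median and mean differed in sign for the denervation, unfolded protein response, Schwann cell, erythroid and satellite cell lists, none of which passed. Some genes are in several lists, such as Cdkn1a and Ddit4.

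The text names genes by a rule: the 10 largest rises and 10 largest falls among clusters past the threshold with 1 symbol and the same direction in 4 of 4 experiments; up to 4 members of each list with the smallest adjusted p; and 12 fixed genes, of which 11 had a cluster. RIKEN clones, predicted genes and olfactory receptors are only described as such. The rule gave 161 genes, of which a part is named; other genes are said to have been chosen after their values were seen.

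The fit was tested on simulated arrays with the real means and experiment effects, in which 200 of 16755 clusters differed by a known amount. It recovered 4% of the clusters changed by 0.5 on the log2 scale, 84% at 1, 98% at 1.5 and 100% at 2, and 7.14% of its 154 calls were unchanged clusters. Changes of 0.5 were thus mostly missed in the simulation. In simulated arrays with independent genes, camera called 0 of 36 unshifted lists over 14860 genes and recovered a list lowered by 0.3; real genes are correlated, which this simulation leaves out. This simulation was written after the first fit of the real values.

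Alternatives were the fit without the block, experiment as a random block, leaving out each experiment, quantile normalization, median centring, leaving out the third of clusters with the lowest mean, a trended and robust prior, array weights, a paired t-test, an adjusted p of 0.1, a 1.5-fold minimum and 1 cluster per gene; for lists also the estimated correlation, fry and averaging a gene's clusters. With the random block and the trended prior, lists were tested by cameraPR on the moderated statistics. The array weights were equal for the fed and the fasted array of each experiment, at 0.63, 1.39, 0.55 and 2.07 in experiments 1 to 4. They thus weighted experiments and not single arrays. Principal components were taken over all clusters of the 8 arrays.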

Results

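The series measured how a 24 h fast changed mRNA levels in the tibialis anterior, a fast-twitch muscle of the mouse lower leg. Male mice aged 8 weeks were fed ad libitum or fasted, and each array was hybridised with a pool of RNA from 3 mice. The experiment was carried out 4 times, each time with 1 fed and 1 fasted pool, which gave 4 fed and 4 fasted exon arrays. Each array held 16755 log2 expression values, 1 per transcript cluster, and the array medians lay between 5.76 and 5.91. Pearson correlations between arrays across transcript clusters, which are not independent replicates, ranged from 0.957 to 0.980. The number of arrays limited the precision, with a median standard error of 0.12 on the log2 scale.

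The comparison asked which mRNAs differed between fasted and fed muscle. Fasted muscle held more mRNA of a set of genes led, among clusters with 1 symbol, by Retreg1, Fbxo32, Pdk4, Mt2 and Klhl38, and less of a smaller set led by Igfbp5, Itgb6, Plcd4 and Ky. In all, 137 of 16755 transcript clusters passed an adjusted p of 0.05 in limma's paired test, 89 higher and 48 lower in fasted muscle. At least a 2-fold difference was seen in 39 of the higher and 15 of the lower ones. All 137 differed in the same direction in 4 of 4 experiments, which selection by a paired test largely sets. Of the 137, 118 carried 1 gene symbol, 77 higher and 41 lower. Of these 118, 116 were the cluster that represented its gene, 77 higher and 39 lower. The count was 16 without experiment 1, 37 without experiment 2, 31 without experiment 4 and 45 after each array was centred on its median. It was 229 with experiment as a random block, 269 without the clusters of lowest mean, 216 with a trended robust prior and 265 with array weights. A paired test without moderated standard errors, which has 3 degrees of freedom, passed 1 cluster, and that cluster was not among the 137.

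The largest rise was that of Retreg1, a receptor for autophagy of the endoplasmic reticulum (transcript cluster 6829281), from a log2 level of 6.99 ± 0.32 in fed to 9.26 ± 0.24 in fasted muscle (SD, n = 4), a 4.82-fold difference (log2 2.27 ± 0.17 SE, adjusted p = 0.00307). Fbxo32, which encodes the muscle ubiquitin ligase atrogin-1 (cluster 6835938), was 4.37-fold higher (log2 2.13 ± 0.13, adjusted p = 0.00084). Pdk4, a kinase that restrains glucose oxidation by inactivating pyruvate dehydrogenase (cluster 6951412), was 3.77-fold higher (log2 1.91 ± 0.11, adjusted p = 0.00084). The metallothionein transcript Mt2 rose by 1.80 ± 0.14, Klhl38 by 1.78 ± 0.19 and the cell cycle inhibitor Cdkn1a by 1.76 ± 0.11 on the log2 scale. Sesn1, a sestrin that restrains mTORC1, rose by 1.51 ± 0.14. The stretch-responsive muscle genes Ankrd2 and Csrp3 rose by 1.48 ± 0.19 and 1.40 ± 0.15, and a RIKEN clone rose by 1.33 ± 0.10. The calls of Klhl38 and Csrp3 ended without experiment 1, at adjusted p of 0.0755 and 0.0737, and that of Csrp3 also without the experiment block, at 0.0698. Ankrd2 did not pass without experiment 1, 3 or 4 (adjusted p of 0.101, 0.0504 and 0.0542) or after median centring (0.0545).

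The largest fall among clusters with 1 symbol was that of Igfbp5, an insulin-like growth factor binding protein (cluster 6759664), from 8.36 ± 0.32 to 6.68 ± 0.18 (SD, n = 4), a log2 change of -1.68 ± 0.12 (SE, adjusted p = 0.00202). The integrin subunit Itgb6 fell by 1.45 ± 0.13, the phospholipase Plcd4 by 1.43 ± 0.13, and Ky, a muscle protein named for the kyphoscoliosis mouse, by 1.41 ± 0.12. The transferrin receptor Tfrc, which imports iron, fell by 1.37 ± 0.21, Stxbp4 by 1.33 ± 0.20, Nrep by 1.28 ± 0.16, Pwwp3b by 1.19 ± 0.15 and the antiproliferative gene Tob1 by 1.12 ± 0.12. A second cluster of Stxbp4 fell by 0.89 ± 0.11. An olfactory receptor cluster that fell by 1.33 ± 0.14 had a low level, 4.16 in fed and 2.82 in fasted muscle. The largest fall of all, -1.97 ± 0.11, was in a cluster without a gene symbol. Igfbp5, Itgb6, Plcd4 and Ky passed in each of 11 alternative settings, as did Retreg1, Fbxo32, Pdk4, Mt2, Cdkn1a, Sesn1, Gadd45a and the RIKEN clone. The 11 settings are refits with limma. The paired test without moderated standard errors is not among them, and none of these genes passed it. Tfrc did not pass without experiment 1, 2 or 4 (adjusted p of 0.141, 0.122 and 0.0542) or after median centring (0.0976), and the larger fall of Stxbp4 did not pass without experiment 1, 3 or 4 (0.167, 0.0831 and 0.112), after quantile normalization (0.0501) or after median centring (0.0760). Leaving out an experiment leaves fewer arrays, so a call can end without a smaller difference. Without experiment 1, 2 or 4, Tfrc was at -1.46, -1.41 and -1.54, against -1.37 with all 4. Other differences shrank, such as that of Csrp3 without experiment 1, to 1.28 from 1.40. Nrep did not pass without experiment 1 or 2 (0.0890 and 0.0819) or after median centring (0.0591), Pwwp3b without experiment 1, 2 or 4 (0.0522, 0.0565 and 0.0516), and the olfactory receptor and Tob1 without experiment 1 (0.0626 and 0.0737).

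**Figure D1:**
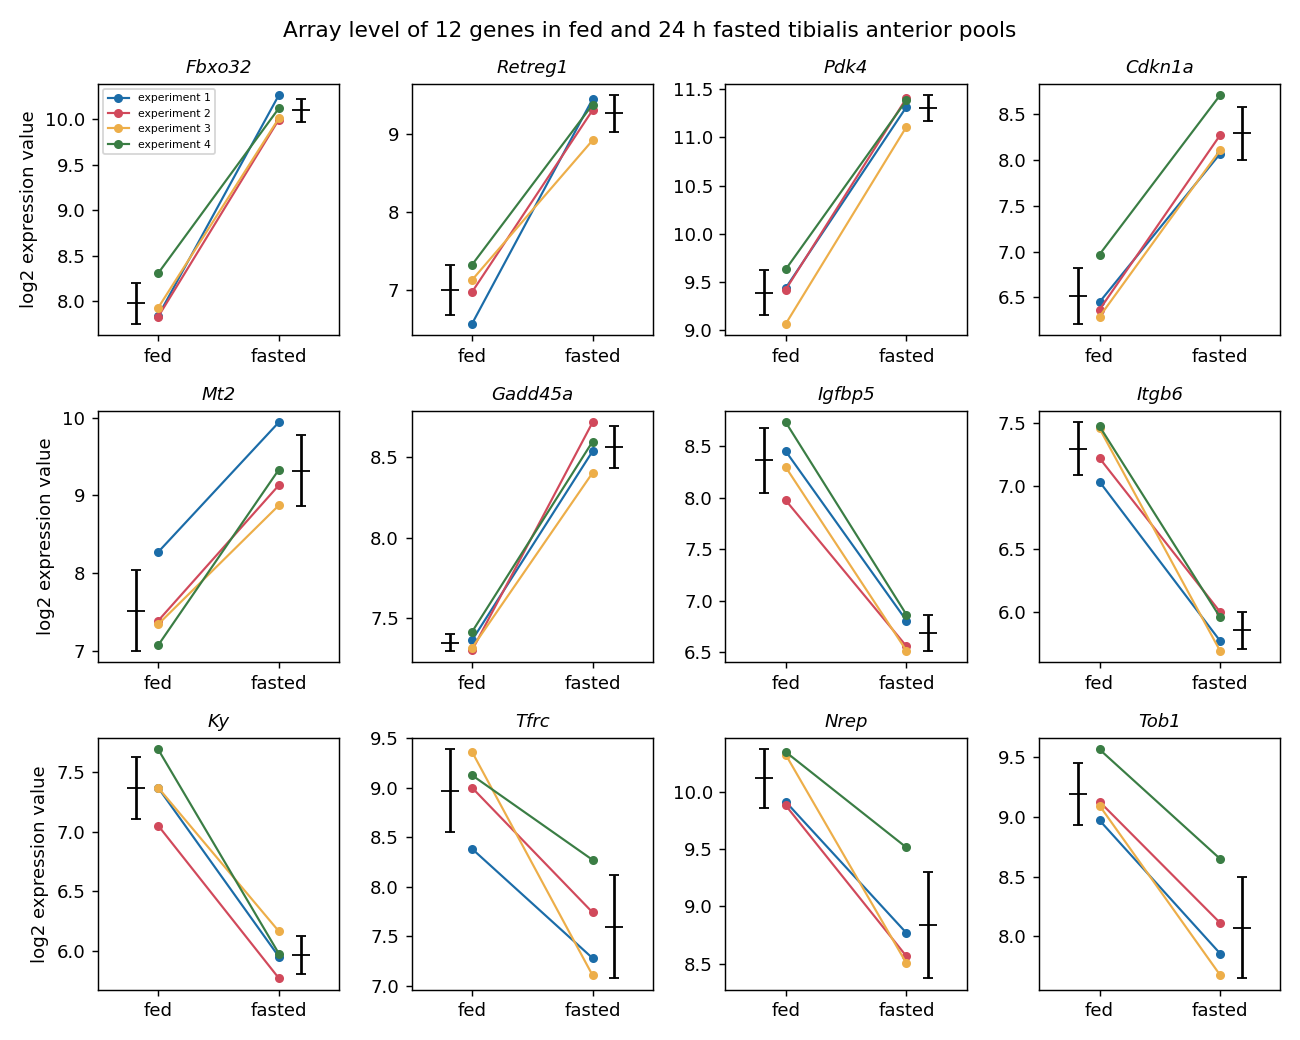
Log2 expression values of 12 genes in fed and fasted pools, with a line joining the 2 pools of each of 4 experiments and a black mark with bars for the mean ± SD of each group. Every line runs upward for the 6 genes that rose, from Fbxo32 to Gadd45a, and downward for the 6 that fell, from Igfbp5 to Tob1.

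The same comparison was read through 36 gene lists. limma's camera test with a preset correlation between genes of 0.01 placed 7 lists higher and 3 lower in fasted muscle at an adjusted p under 0.05. Such a count is also reached by other splits of the arrays. Without the block, 10 of 35 splits into 4 and 4, the real one among them, gave at least 10 lists, and the highest other gave 17. None of the 36 passed when the correlation was estimated from the 8 arrays, where the smallest adjusted p was 0.152. That setting changes more than the correlation, as it refers camera's statistic to the 3 residual degrees of freedom. The estimated correlation was -0.017 for the ribosome biogenesis list and -0.054 for the mitochondrial biogenesis list, below the preset 0.01. Their unadjusted camera p still rose, from 3.9e-06 to 0.0147 and from 0.0061 to 0.0598. A call lost in that setting is thus not the effect of correlation alone. In an exact permutation of the arrays, two-sided and added after the data were seen, 4 of the 10 lists reached the smallest possible p of 0.0286, namely the ubiquitin-proteasome, ATF4, glucocorticoid and ribosome biogenesis lists, with an adjusted p of 0.257; an adjusted p under 0.05 would have needed at least 21 of the 36 lists at that smallest p, so the adjusted value says little. Against 2000 random lists matched on mean level, also added after the data were seen, the medians of the ATF4, oxidative phosphorylation and mitochondrial biogenesis lists lay at percentiles 83.0, 5.15 and 2.90, that of the matrix list at 0, that of the ribosome biogenesis list at 99.95 and those of the other 5 of these 10 lists at 100. Random lists carry none of the correlation between genes of the same list. Where that correlation is positive, a percentile near 0 or 100 is thus reached too easily. The counts of member genes that passed the test over all clusters are given first for each list.

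In the list of ubiquitin-proteasome genes of muscle atrophy, 3 of 14 measured members rose and none fell over all clusters, and 10 rose when adjusted over the list alone. Besides Fbxo32, these were the ubiquitin ligase genes Fbxo30 (log2 0.90 ± 0.13, adjusted p = 0.0330) and Ube4a (1.08 ± 0.18, adjusted p = 0.0439). The proteasome subunit Psmd4 did not pass over all clusters, at 0.46 ± 0.11 (adjusted p = 0.132). The list median was 0.46 (camera adjusted p = 8.7e-13, and adjusted p = 0.328 with an estimated correlation). Trim63, the other well-known ligase of muscle atrophy, was not analysed here. Fbxo30 and Ube4a did not pass when any 1 of the 4 experiments was left out, with adjusted p up to 0.128 and 0.157, or after median centring (0.0760 and 0.105).

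Of 21 measured autophagy and lysosome genes, 1 rose and none fell over all clusters, and 8 rose when adjusted over the list alone. The gene that passed was Gabarapl1, which encodes an autophagosome protein of the Atg8 family, at 1.18 ± 0.11 (adjusted p = 0.00699). The autophagy kinase Ulk1 (0.64 ± 0.11), the cargo receptor Sqstm1 (0.63 ± 0.12) and the lysosomal protease Ctsl (0.52 ± 0.10) had adjusted p of 0.0568, 0.0620 and 0.0773, and passed in 4, 5 and 4 of 11 alternative settings. The list median was 0.23 (camera adjusted p = 2.7e-05, and adjusted p = 0.349 with an estimated correlation). Without experiment 1, the adjusted p of Gabarapl1 was 0.0522.

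In the list of insulin and FoxO signalling, 2 of 19 measured members rose, Cdkn1a and Sesn1, and 1 fell, Igfbp5. When adjusted over the list alone, 11 rose and 3 fell. The insulin receptor gene Insr was at 0.58 ± 0.11 (adjusted p = 0.0743) and passed in 5 of 11 alternative settings. The transcription factor genes Foxo1 and Foxo3 did not pass, at 0.35 ± 0.14 (adjusted p = 0.399) and 0.32 ± 0.11 (adjusted p = 0.338), and neither did the growth factor gene Igf1, at -0.61 ± 0.13 (adjusted p = 0.111), which passed in 1 of them. The list median was 0.35 (camera adjusted p = 4.7e-06, and adjusted p = 0.328 with an estimated correlation).

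The glucocorticoid response list had the most members past the test, 7 of 19 higher and none lower, and 13 higher when adjusted over the list alone. These included Cdkn1a, which is also in the insulin and FoxO list, Mt2, the glutamine synthetase gene Glul (log2 1.16 ± 0.13, adjusted p = 0.0136), Fkbp5, a co-chaperone of the glucocorticoid receptor (1.28 ± 0.15, adjusted p = 0.0141), and the mTORC1 inhibitor gene Ddit4 (0.98 ± 0.12, adjusted p = 0.0192). The other members that rose, named after their values were seen, were Mt1 (1.17 ± 0.18) and Errfi1 (0.75 ± 0.11). Glul rose from a log2 level of 10.31 ± 0.15 to 11.47 ± 0.14 (SD, n = 4). The list median was 0.46 (camera adjusted p = 1.5e-19, and adjusted p = 0.152 with an estimated correlation). Glul did not pass without experiment 1 or 2 (adjusted p of 0.0737 and 0.0616), Fkbp5 without experiment 1 (0.0623) and Ddit4 without experiment 1 or 4 (0.0939 and 0.0910). Mt1 did not pass when any 1 of the 4 experiments was left out (adjusted p from 0.0755 to 0.0979), after quantile normalization (0.0681) or after median centring (0.0655), and Errfi1 did not pass without experiment 1, 2 or 4 (0.137, 0.157 and 0.164) or after median centring (0.0760). Mt1 and Mt2 are close paralogs, so their probes can share signal.

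The amino acid response list, built around the transcription factor ATF4, was split. Of 24 measured members, 3 rose and none fell over all clusters, while 6 rose and 2 fell when adjusted over the list alone. The stress-inducible Gadd45a rose by 1.21 ± 0.11 (adjusted p = 0.00513), Ppp1r15a, which directs dephosphorylation of eIF2alpha, by 1.24 ± 0.14 (adjusted p = 0.0134), and Ddit4 as above. Chac1 was at 0.61 ± 0.11 (adjusted p = 0.0568, passing in 5 of 11 alternative settings) and Atf4 itself at 0.40 ± 0.11 (adjusted p = 0.218). Values of 12 members lay above 0 and of 12 below, and the list median was 0.02 against a mean of 0.17 (camera adjusted p = 0.0194, and adjusted p = 0.328 with an estimated correlation). The list did not pass without experiment 3 (adjusted p = 0.0691), and the call of Ppp1r15a ended without experiment 1 (adjusted p = 0.0737).

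Neither chaperone list passed. None of 16 genes of the unfolded protein response passed over all clusters, and 2 were higher when adjusted over the list alone. The co-chaperone gene Dnajb9 was at 1.00 ± 0.19 (adjusted p = 0.0698) and Edem1, of endoplasmic reticulum-associated degradation, at 0.55 ± 0.10 (adjusted p = 0.0710), and they passed in 7 and 5 of 11 alternative settings, with adjusted p down to 0.0206 and 0.0167; the list median was -0.01 and the mean 0.05 (camera adjusted p = 0.607). Of 10 heat shock genes, Hspb7, a small heat shock protein of muscle, rose by 0.91 ± 0.14 (adjusted p = 0.0398), and 2 were higher when adjusted over the list alone (median 0.06, camera adjusted p = 0.124). The call of Hspb7 ended without each experiment in turn, with adjusted p up to 0.154, without the block (0.0557), after quantile normalization (0.0505) and after median centring (0.0760).

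Among 27 measured genes of fatty acid oxidation and its PPAR-driven programme, 4 rose and none fell over all clusters, and 5 rose when adjusted over the list alone. They were Pdk4, the mitochondrial uncoupling protein gene Ucp3 (log2 1.02 ± 0.11, adjusted p = 0.0136), Pnpla2, which encodes the triglyceride lipase ATGL (1.06 ± 0.13, adjusted p = 0.0188), and the acyl-CoA thioesterase gene Acot2 (0.98 ± 0.12, adjusted p = 0.0192). The list median was 0.21 (camera adjusted p = 1.7e-09, and adjusted p = 0.328 with an estimated correlation). Ucp3 did not pass without experiment 1, 2 or 4 (adjusted p of 0.0737, 0.0616 and 0.0716), Pnpla2 without experiment 1 or 4 (0.0737 and 0.0761) or after median centring (0.0529), and Acot2 without experiment 1 or 4 (0.0924 and 0.0910). Acot2 has a close paralog, and a further cluster carried the symbols of both. Beside this list, the adipocyte marker Plin4 was higher in fasted muscle, at 0.68 ± 0.10 (adjusted p = 0.0330), a call that ended without each experiment in turn (adjusted p of 0.125, 0.157, 0.0631 and 0.149) and after median centring (0.0545).

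Lists of lipid synthesis and of glucose use held no member past the test over all clusters. Of 17 lipogenic genes, 1 was higher and 1 lower when adjusted over the list alone, the acetyl-CoA carboxylase gene Acacb (0.51 ± 0.10, adjusted p = 0.0860 over all clusters, passing in 2 of 11 alternative settings) and the transcription factor gene Mlxipl (-0.40 ± 0.10, adjusted p = 0.172); the median was -0.09 (camera adjusted p = 0.318). Of 17 cholesterol synthesis genes, Fdft1 (0.59 ± 0.12, adjusted p = 0.0911, passing in 3 of 11) was higher when adjusted over the list alone, while the median was -0.13 (camera adjusted p = 0.216). Glycolysis and glycogen genes had a median of -0.01 over 21 members (camera adjusted p = 0.688), with the muscle fructose bisphosphatase gene Fbp2 at 0.50 ± 0.12 (adjusted p = 0.154). The tricarboxylic acid cycle list had a median of -0.10 over 20 members (camera adjusted p = 0.0897). It passed in 2 of 12 alternative camera settings at the preset correlation, with adjusted p from 0.00107 to 0.847.

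The lists of oxidative phosphorylation and mitochondrial biogenesis had medians slightly below 0, with no single gene past the test over all clusters or when adjusted over the list alone. Of 28 measured oxidative phosphorylation genes, 27 had values below 0, among them Cox7b (-0.43 ± 0.12, adjusted p = 0.225) and Cyc1 (-0.26 ± 0.10, adjusted p = 0.373). The median was -0.11 (camera adjusted p = 0.00458, and adjusted p = 0.565 with an estimated correlation), 5.15% of random lists matched on mean level had a lower median, and the list did not pass without experiment 3 (adjusted p = 0.549). The list of mitochondrial biogenesis and its coactivator PGC-1 had a median of -0.12 over 17 members (camera adjusted p = 0.0220, and adjusted p = 0.328 with an estimated correlation). In it, Ppargc1a was at -0.39 ± 0.13 (adjusted p = 0.292) and Vegfa at -0.26 ± 0.10 (adjusted p = 0.373). This list did not pass without experiment 3 (adjusted p = 0.147) or experiment 4 (adjusted p = 0.0756).

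Of 22 ribosome biogenesis genes, the nucleolar gene Gnl3 rose by 0.98 ± 0.13 (adjusted p = 0.0250), and 4 were higher when adjusted over the list alone, among them Tsr1 (0.47 ± 0.11) and Ddx21 (0.49 ± 0.13). The median was 0.16 (camera adjusted p = 2.3e-05, and adjusted p = 0.265 with an estimated correlation). The call of Gnl3 ended without experiment 1, 2 or 4, with adjusted p of 0.114, 0.118 and 0.101, and after median centring (0.0695). Cytosolic ribosomal protein genes had a median of -0.08 over 12 members (camera adjusted p = 0.530), and translation factors with tRNA synthetases a median of 0.08 over 18 (camera adjusted p = 0.160). No member of either passed, including the cap-binding factor gene Eif4e at -0.76 ± 0.20 (adjusted p = 0.177).

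Of 29 measured extracellular matrix and collagen genes, 25 had values below 0, none passed over all clusters, and 8 were lower when adjusted over the list alone. These included tenascin C, Tnc (-0.58 ± 0.10, adjusted p = 0.0602 over all clusters), lumican, Lum (-0.95 ± 0.19, adjusted p = 0.0899), which passed in 6 and 3 of 11 alternative settings with adjusted p down to 0.0220 and 0.0341, and the collagen genes Col1a2 (-0.45 ± 0.11, adjusted p = 0.169) and Col6a3 (-0.43 ± 0.12, adjusted p = 0.195). The median was -0.18 (camera adjusted p = 2.5e-06, and adjusted p = 0.438 with an estimated correlation), and p was 0.114 in the exact permutation of the arrays. Of 4 tendon genes examined, Tnmd was at -0.73 ± 0.13 (adjusted p = 0.0652) and Scx at -0.70 ± 0.15 (adjusted p = 0.108). Both had values below 0 in 4 of 4 experiments and passed in 3 and 2 of the 11 settings. Comp (-0.07 ± 0.11) and Thbs4 (-0.06 ± 0.13), chosen after the values were seen, lay near 0. Thbs4 is also a member of the matrix list.

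**Figure D2:**
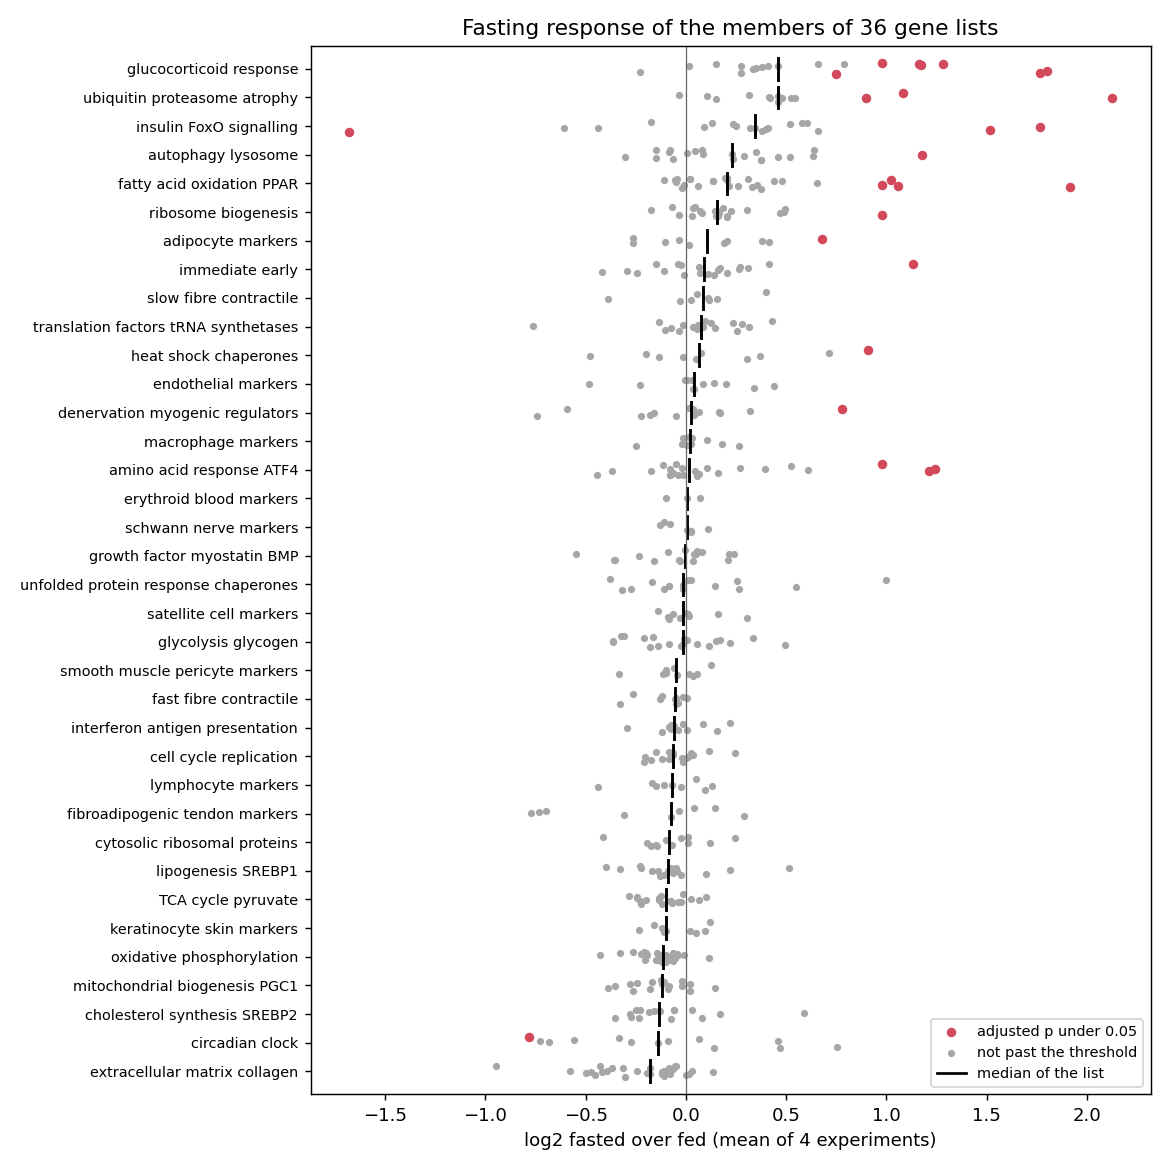
Log2 difference of fasted over fed, as the mean of 4 experiments, for each measured member of 36 gene lists, ordered by list median. Red points passed an adjusted p of 0.05 over all clusters, grey points did not, and black bars are list medians, from 0.46 for the glucocorticoid response to -0.18 for extracellular matrix and collagen.

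Contractile and regulatory lists of muscle did not pass the list test. Fast fibre genes had a median of -0.05 over 10 members (camera adjusted p = 0.146) and slow fibre genes of 0.08 over 8 (camera adjusted p = 0.688), with the calsequestrin gene Casq2 at -0.39 ± 0.10 (adjusted p = 0.178). Of 14 genes of denervation and myogenic regulation, Ankrd1 rose by 0.78 ± 0.13 (adjusted p = 0.0439), while Mef2c (-0.59 ± 0.13) and Hdac9 (-0.74 ± 0.17) were lower when adjusted over the list alone and passed over all clusters in 1 and 3 of 11 alternative settings; the median was 0.03, the mean -0.02 and the camera adjusted p 0.935. The call of Ankrd1 ended without each experiment in turn, with adjusted p up to 0.191, without the block (adjusted p = 0.0904), with a random block (0.0691), after quantile normalization (0.0630) and after median centring (0.0654). The myostatin and BMP list had a median of -0.0023 and a mean of -0.05 over 17 members (camera adjusted p = 0.607), with Smad3 at -0.55 ± 0.10 (adjusted p = 0.0715, passing in 5 of the 11 settings) and the myostatin gene Mstn at 0.24 ± 0.20 (adjusted p = 0.785).

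Among 13 circadian clock genes, Bhlhe40, a transcriptional repressor of the clock, fell by 0.78 ± 0.12 (adjusted p = 0.0337), and 2 were higher and 4 lower when adjusted over the list alone. Arntl, which encodes the activator BMAL1, was at 0.75 ± 0.14 and the clock output gene Dbp at -0.68 ± 0.13, both with an adjusted p of 0.0679 and each passing in 3 of 11 alternative settings. The list median was -0.14 (camera adjusted p = 0.175), and the call of Bhlhe40 ended without each experiment in turn, with adjusted p up to 0.164, and after median centring (0.0760). Of 20 immediate early genes, Btg2 rose by 1.13 ± 0.15 (adjusted p = 0.0208). This call ended without experiment 2 or 4 (adjusted p of 0.0888 and 0.0772) and after quantile normalization (0.0503). The list median was 0.09 (camera adjusted p = 0.0897). The list passed in 2 of 12 alternative camera settings at the preset correlation, with medians from -0.05 to 0.23 and adjusted p from 0.00077 to 0.693. Cell cycle genes had a median of -0.06 over 17 members (camera adjusted p = 0.606), and interferon and antigen presentation genes of -0.06 over 13 (camera adjusted p = 0.688), with no member past the test.

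Marker lists of other cell types were measured beside these. Of 10 adipocyte markers, the lipid droplet gene Plin4 rose by 0.68 ± 0.10 (adjusted p = 0.0330), and 3 were higher when adjusted over the list alone, including Fabp4 (0.38 ± 0.11, adjusted p = 0.235); the median was 0.10 (camera adjusted p = 0.123). The call of Plin4 ended without each experiment in turn, with adjusted p up to 0.157, and after median centring (0.0545). The list of fibroadipogenic and tendon markers had a median of -0.07 and a mean of -0.24 over 9 members (camera adjusted p = 0.0924). It passed in 2 of 12 alternative camera settings at the preset correlation, with adjusted p from 0.00754 to 0.309. When adjusted over the list alone, 3 members were lower, Tnmd, Scx and Thy1 (-0.77 ± 0.18, adjusted p = 0.141 over all clusters, passing in 1 of 11 alternative settings). Endothelial markers had a median of 0.04 over 12 members, with 1, Kdr, lower when adjusted over the list alone (-0.48 ± 0.12; camera adjusted p = 0.289). Macrophage markers had a median of 0.02 (camera adjusted p = 0.501), lymphocyte markers of -0.07 (0.596), smooth muscle and pericyte markers of -0.05 (0.686) and keratinocyte markers of -0.10 (0.686). Satellite cell markers had a median of -0.01 (camera adjusted p = 0.865), Schwann cell and nerve markers of 0.0040 (0.865), and the 3 measured erythroid markers of 0.0048 (0.902), each opposite in sign to its mean of 0.0093, -0.02 and -0.0086. No member of the last 7 lists passed over all clusters or when adjusted over its list alone.

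**Figure D3:**
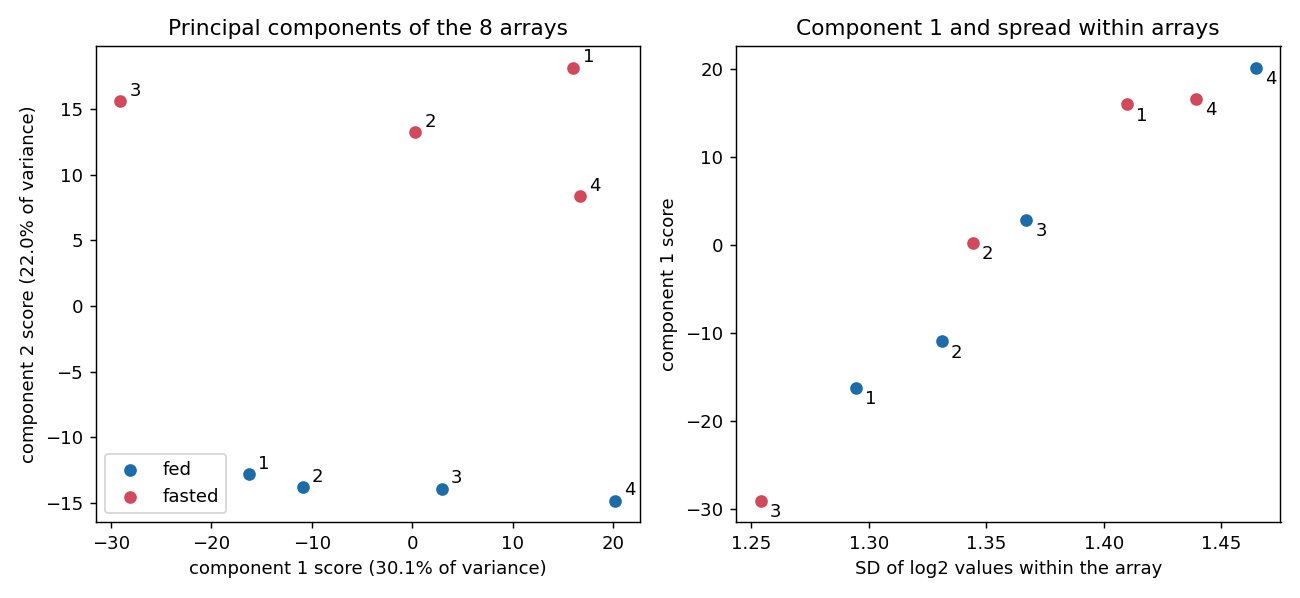
Scores of the 8 arrays on the first 2 principal components (30.1% and 22.0% of the variance, left) and the first score against the SD of log2 values within each array (right), with points numbered by experiment. Fed and fasted arrays separate on component 2, and the component 1 score increases with the spread within the array.

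The arrays also differed within each group. On component 1, with 30.1% of the variance, fed and fasted arrays overlapped (exact permutation test, two-sided, p = 0.943, n = 4 and 4), while on component 2, with 22.0%, they separated (p = 0.0286 in the same exact test, the smallest that 4 against 4 arrays allow). Neither comparison was fixed beforehand, and p was not adjusted for testing 2 components. The fasted array of experiment 3 had the lowest SD of log2 values, 1.25. The mean array SD was 1.36 ± 0.07 in fed and 1.36 ± 0.08 in fasted muscle (SD, n = 4).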

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

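The comparison of fed with fasted arrays on component 1 was chosen after the result was seen, as was the correlation after quantile normalization. Single pools stood far from the other 3 of their group, by the gap to the nearest value over the group's range, in 17 of 402 groups of 4 arrays checked (198 genes and 3 array measures in each group), against 20.1 that chance gives at 1 in 20. All are log2 levels.

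In fed muscle, the myostatin gene Mstn was at 8.35 in experiment 1, against 8.71 to 8.77 in the other pools, and Nfil3, a clock-related repressor, at 7.97 against 7.13 to 7.19. Experiment 2 had low fed levels of the tendon gene Tnmd (7.68 against 8.45 to 8.59), the matrix gene Dcn (10.19 against 10.52 to 10.56) and the proton pump gene Atp6v1h (5.49 against 5.82 to 5.86). Ankrd1 was at 6.14 in fed experiment 3, against 6.81 to 6.82. Fed experiment 4 was high for Sqstm1 (8.97 against 8.55 to 8.60) and Id3 (6.28 against 5.90 to 5.95).

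In fasted muscle, experiment 1 was high for Acaca (5.75 against 5.28 to 5.32), Cd34 (7.51 against 7.08 to 7.15) and Atp6v1h (7.15 against 6.55 to 6.63). Pi16 was at 6.29 in experiment 2, against 6.43 to 6.45. Experiment 4 was low for the clock gene Cry1 (5.70 against 5.90 to 5.93) and high for the lipase gene Pnpla2 (9.67 against 9.10 to 9.20), Cidea (5.42 against 5.03 to 5.09), Pdgfrb (6.51 against 6.16 to 6.21) and Fhl3 (9.85 against 8.94 to 9.07).

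The leading component of the 8 arrays, with 30.1% of the variance, followed the SD of values within each array (Pearson r = 0.979, exact permutation p = 2.48e-05, the smallest possible; Spearman rho = 1, exact permutation p = 4.96e-05; r = 0.970 without the 2 arrays farthest from the median SD). Feeding state is argued against as its source, since fed and fasted arrays overlapped on it (exact permutation p = 0.943). The spread within arrays, which may come from RNA quality, amplification or the authors' normalization, stays open. Quantile normalization, which gives every array the same spread, lowered the share of the leading component by 17.0% of itself, but the leading component after it no longer followed the array SD (Pearson r = 0.098, exact permutation p = 0.808; Spearman rho = 0, exact permutation p = 1; r = -0.658 without the 2 arrays), so the 2 shares belong to different components and their ratio decides nothing. No biological explanation other than feeding was tested.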

How the results depend on the processing

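Among the settings compared here, only the exact permutation of lists was added after the data were seen. Of 137 clusters (89 higher, 48 lower), 117 also passed without the replicate block, which gave 185, and lists were 10 either way. Counts rose to 229 (143 higher, 86 lower) with a random block, 269 (161, 108) without the clusters of lowest mean, which tests fewer, 216 (86 lower) with a trended robust prior, 265 (153, 112) with array weights and 251 (149, 102) at an adjusted p of 0.1. They fell to 45 (32, 13) with median centring, all 45 shared; the cause was not tested. The paired t-test, with 3 degrees of freedom, passed 1 cluster (0 higher, 1 lower), not among the 137, against 1625 at an unadjusted p under 0.05 and 1833 for limma. Leaving out 1 experiment, which leaves fewer arrays, gave 16 to 94 clusters (11 to 68 higher, 5 to 26 lower): 16 without experiment 1, 37 without 2, 94 without 3 and 31 without 4. Of 10 lists (7 higher, 3 lower), leaving out 1 experiment gave 8 to 12 (7 to 8 higher, 1 to 4 lower), the estimated correlation 0 (0 higher, 0 lower), fry 4 (3 higher, 1 lower) and the exact permutation of arrays 4 (4 higher, 0 lower) at the smallest possible unadjusted p of 0.0286, adjusted 0.257, where 21 lists at that p would have been needed to pass. The other settings gave 10 or 11 lists. Some lists that were not called passed in a few of 12 alternative camera settings at the preset correlation. Those of the tricarboxylic acid cycle, immediate early genes and fibroadipogenic and tendon markers passed in 2. Those of heat shock genes, translation factors with tRNA synthetases and adipocyte markers passed in 1. No result changed direction past the threshold. Of 37 genes called by the naming rule, 12 passed in all 11 refits; 24 calls ended without experiment 1, 13 without 2, 8 without 3 and 16 without 4, 12 with median centring, 4 with quantile normalization, 3 without the block and 1 with a random block. Of the other 124 named by the rule, 10 passed without the block, 14 with a random block, 3 with quantile normalization, 19 of 112 without the clusters of lowest mean, 11 with a trended robust prior, 17 with array weights and 1 without experiment 3. Among scalings, the share of higher clusters was 65.0% as deposited, 67.8% and 71.1%, and the median difference of all clusters stayed within 0.1. Low-signal clusters could not be set apart from background here.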

Other observations

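The genes of the first 2 paragraphs were chosen after their values were seen, as were the tests of fibroblast and tendon genes and the test of 8 clock genes below; the criteria for the fibroblast, tendon and matched clock sets were changed after their values were known. Outside the fixed lists, the cholesterol exporter gene of lysosomes Npc1 rose by 1.26 ± 0.12 (SE, log2; limma adjusted p = 0.00620), the proton pump subunit gene Atp6v1h by 0.97 ± 0.13 (adjusted p = 0.0268) and Atg13, of the autophagy initiation complex, by 0.69 ± 0.12 (adjusted p = 0.0490). The mitochondrial acetyl-CoA synthetase gene Acss1 rose by 0.99 ± 0.11, the catalase gene Cat by 0.85 ± 0.11, the pantothenate kinase gene Pank1 by 0.78 ± 0.10 and the phosphatidate phosphatase gene Lpin1 by 0.69 ± 0.10. The imprinted zinc finger gene Peg3 rose by 1.31 ± 0.11 (adjusted p = 0.00428). The muscle genes Xirp1, Mustn1 and Fhl3 rose by 0.94 ± 0.15, 0.87 ± 0.13 and 0.84 ± 0.12, in the direction of Ankrd1, Ankrd2 and Csrp3. Of these, Npc1 and Peg3 passed in all 11 refits. The other 9 did not pass without experiment 1 or without experiment 4, and all of them but Acss1 did not pass without experiment 2, nor Atg13, Lpin1, Xirp1 and Mustn1 without experiment 3, with adjusted p up to 0.205 for Atg13. All but Acss1 and Pank1 also lost the call after median centring (up to 0.0983 for Atg13), Xirp1 after quantile normalization (0.0946), Atg13 and Fhl3 without the block (0.0510 and 0.227) and Fhl3 with a random block (0.177).

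The chloride channel gene Clcn1, which sets the resting conductance of muscle fibres, fell by 0.84 ± 0.11 (limma adjusted p = 0.0247), the water channel gene Aqp4 by 0.71 ± 0.11 and the bicarbonate transporter gene Slc4a4 by 0.69 ± 0.12. Prkag3, the muscle subunit of AMP-activated protein kinase, fell by 0.87 ± 0.10 (adjusted p = 0.0159), the kinase gene Map2k6 by 0.91 ± 0.15, the insulin receptor adaptor gene Grb14 by 0.72 ± 0.12, the peroxisomal transporter gene Abcd2 by 0.99 ± 0.14 and the transcriptional repressor gene Bcl6 by 0.93 ± 0.12. None of the 8 passed without experiment 1, 2 or 4, and Aqp4, Slc4a4, Map2k6 and Grb14 did not pass without experiment 3 either, with adjusted p up to 0.199 for Grb14. All but Prkag3 also lost the call after median centring (up to 0.131 for Map2k6), Slc4a4, Map2k6 and Grb14 after quantile normalization (0.0618, 0.0509 and 0.0527), and Clcn1 and Bcl6 without the block (0.0536 and 0.0592).

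The number of clusters without the block was compared over the 35 splits of the 8 arrays into 4 and 4. The real split gave 185 clusters, and the highest other gave 1. Chance is thus unlikely but not excluded, as 1 of 35 is the smallest share these splits can give. They leave out the pairing, and the other splits mix fed with fasted arrays, which can add a feeding effect to the spread within their groups. With the block, 8 splits part all 4 experiments, too few for a share under 0.05; the real one gave 137 and the highest other 0. For gene lists called by camera without the block, chance cannot be excluded: 10 of the 35 splits gave as many as the real 10, and the highest other gave 17. With the block the real split gave 10 lists and the highest of the other 7 gave 9, again with too few splits for a share under 0.05.

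Of 29 matrix genes, 25 had values below 0 and none passed over all clusters, though Tnc and Lum passed in 6 and 3 of 11 alternative settings; the list passed camera with the preset correlation (adjusted p = 2.5e-06) but not with an estimated correlation (adjusted p = 0.438), by fry (adjusted p = 0.0793) or in an exact permutation of the arrays, added after the data were seen, where 4 of 35 splits shifted it as far (p = 0.114). These splits leave out the pairing of the arrays. The list mean was -0.349, -0.102, -0.222 and -0.248 in experiments 1 to 4. A shift of all genes at the signal level of the matrix genes is argued against, since 0% of 10000 random lists matched on mean level had a median as low as -0.18. Fewer fibroblasts in the fasted samples may contribute and stay open: the mean of Pdgfra, Pdgfrb, Dpt, Pi16, Cd34 and Thy1 lay above that of the matrix list by 0.124 ± 0.082 (SD over 4 experiments), but the markers split, with Thy1 (-0.77 ± 0.18, SE) and Cd34 (-0.31 ± 0.12) below 0 and Pdgfra (0.29 ± 0.11) above 0, each in 4 of 4 experiments. Less tendon in the fasted samples may contribute and stays open: tendon genes averaged -0.388 ± 0.135 (SD over 4 experiments), but this came from Scx (-0.70) and Tnmd (-0.73), while Comp (-0.07) and Thbs4 (-0.06) lay within their standard errors of 0.

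Of 13 clock genes, whose list did not pass (camera adjusted p = 0.175), Bhlhe40 passed over all clusters (adjusted p = 0.0337) and no other member did, though Arntl, Dbp and Bhlhe41 passed in 3, 3 and 4 of 11 alternative settings. Arntl was at 0.75 ± 0.14, and Dbp, Hlf, Bhlhe40 and Bhlhe41, of another phase, averaged -0.687, while Per1 (0.46 ± 0.12, adjusted p = 0.184) and Cry1 (-0.14 ± 0.10, adjusted p = 0.756) lay against such a split, each with its sign in 4 of 4 experiments. Per1 is also a member of the glucocorticoid response list, so its value need not speak to the clock alone. As a hypothesis, the fed and fasted pools may differ in clock phase, through feeding or the hour of harvest, which is not given in the sources used here, so feeding and hour cannot be told apart. In 6 genes set beforehand, the mean of Clock, Npas2 and Nfil3 lay above that of Tef, Per3 and Nr1d2 by 0.456 ± 0.365 (SD over 4 experiments), at -0.075 in experiment 1, and with Cry1 and Per1 counted in by 0.192 ± 0.309, which leaves the hypothesis open. Of matched random sets, 2.86% differed as much as the 6 genes and 14.3% as much as the 8. These shares tell how widely sets of so few genes scatter, so they do not decide whether all genes at that level shifted.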
